A study of Mus musculus with 48 samples.

How the data were processed

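Hippocampal microglia of 48 BALB/cByJ mouse pups aged 17 days were profiled on the nCounter mouse glial panel, which counts RNA molecules directly with fluorescent barcoded probes and without amplification. Per the labels' protocols, about 60000 microglia per animal were purified by Percoll gradient and flow cytometry, lysed and hybridised without RNA extraction. The pups belonged to 3 rearing groups named CTL, LB and UPS in the labels, with 16 animals per group and 8 per group and sex. The 48 libraries were run in 4 batches of 12, and each batch held 2 libraries of every rearing group and sex. Batch and rearing are therefore balanced. Per the labels' protocols the animals of each group and sex came from 4 to 5 litters, so some were littermates. Litter was not used here, and p-values that treat littermates as independent are too small if littermates resemble each other.

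The data were tables of the authors' own comparisons, 1 for each of 3 pairs of rearing groups, each with the same 478 genes. Per the file headers they hold a log2 fold change, a linear fold change (a ratio), a p-value and a Benjamini-Hochberg adjusted p-value for each gene. Per the series text the authors first ran a multivariate analysis of variance on genes above 20 counts and then the advanced analysis of nSolver for each pair, with batch as a covariate. The normalization, the housekeeping genes and the software version are not given in the sources used here. Values per library were not analysed here, so counts per library and their depth are unknown, and no mean, SD or per-animal direction could be given. The linear fold change equalled 2 to the power of the log2 column to within 0.494%. Of the 478 gene symbols, 476 matched a mouse gene table of the GRCm38.p6 assembly and 2 did not. No genome build is named with the tables, so no coordinates are given.

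The headers do not say which group of a pair is the numerator. The LB and UPS log2 ratio equalled the CTL and UPS ratio minus the CTL and LB ratio to within 0.003 for every gene (median difference 5e-05), and this holds both for later-named over first-named group and for the reverse. Signs are given as deposited and no gene is said to be higher in a named group.

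No model was refitted. The deposited p-values were adjusted by the Benjamini-Hochberg method over the 478 genes of each table, and a gene passed at an adjusted p below 0.05. The same genes passed by the authors' deposited adjusted p column. Standard errors were recovered from each deposited log2 ratio and its two-sided p with a t distribution. Among 6 candidate models, the residual degrees of freedom of 42, which belong to 1 model of all 48 libraries with rearing and batch, gave standard errors that differed least between the tables of a gene (median mismatch 0.144%). Models of all 48 libraries with sex added (0.160%), with rearing and sex (0.163%) or with rearing alone (0.179%) lay close to it, so the choice among these is not settled, while fits of 2 groups gave 0.524% without and 0.695% with batch. The plan had assumed fits of 2 groups and deposited standard errors. The recovered standard error was the same for the 3 comparisons of a gene and gave the 95% intervals. Its median was 0.050 on the log2 scale (range 0.022 to 0.40), at which a 95% interval excludes changes above 0.10, or 1.07-fold.

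Before the data were examined, 24 gene lists were fixed: homeostatic microglia, disease-associated microglia, TREM2 signalling, phagocytosis receptors and opsonins, complement, lysosome, autophagy, cholesterol and lipid handling, type I interferon response, inflammatory cytokines and NF-kB, antigen presentation, cell cycle, glycolysis and hypoxia, glucocorticoid-responsive genes, immediate early and dissociation genes, TGF-beta signalling, growth factor and cytokine receptor signalling, and markers of 7 other cell classes. The 17 lists with at least 3 measured members were tested with limma's cameraPR on the signed normal quantile of the deposited p, with a preset correlation between genes of 0.01, two-sided, adjusted over the 17 lists. A correlation between genes could not be estimated from tables without values per library.

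The genes named were also chosen by a rule fixed then. In each comparison these were the 12 largest log2 ratios of each sign among genes past the threshold, or, where fewer than 5 passed, the 5 smallest p-values of each sign. Up to 4 members per list with the smallest p were added, as were Trem2, Tyrobp, P2ry12, Tmem119, Cx3cr1, C1qa, C3, Itgam, Apoe, Mertk and Csf1r where measured. C3 was not measured, and some genes that the rule names are not reported here. Between the UPS comparisons, up to 12 genes past the threshold in both were named. Other genes past the threshold are named to complete a count of 36 genes and were chosen after their values were seen.

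The ratios against CTL share 16 control libraries. Their correlation and covariance across genes were set beside 1000 simulated pairs of comparisons with no effect, drawn with the recovered standard errors. UPS was also set against the mean of CTL and LB with a standard error of its own from the same model, since this contrast is independent of the CTL and LB ratio.

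Alternatives were the Benjamini-Yekutieli method, an adjusted p below 0.10, an unadjusted p below 0.05, adjustment over the 3 tables together, a minimum of 1.2-fold, centring on the median gene, correlations of 0 and 0.05 between list members, ranks or log2 ratios as the list statistic, 10000 random lists of the same size, and lists without shared members. Moderated variances, list statistics over the recovered standard error, adjustment of the lists of 3 comparisons together, random lists matched on standard error and correlations of ratios per standard error were added after the data had been seen.

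The steps were tested on simulated data with 478 genes and the groups of the CTL and UPS comparison, of which 200 had a known change. The recovered standard errors had a median error of 0.0770%. The share of changed genes past the threshold was 38% at a log2 change of 0.1, 82% at 0.2, 92% at 0.3 and 98% at 0.5, and 5 of 263 genes without a change passed. A list of 15 genes shifted by 0.15 had an adjusted p of 0.00863 with cameraPR. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.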

Results

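Microglia, the resident macrophages of the brain, were compared between 3 rearing groups of mouse pups at 17 days of age, with 16 animals in each of CTL, LB and UPS. CTL is the control group per the labels. As background, LB and UPS are early-life stress models in which pups are reared with limited bedding and nesting material (LB) or with added unpredictable stress (UPS). Transcripts of 478 genes of a glial panel were counted in hippocampal microglia of both sexes, and each pair of groups was compared with the sexes pooled. The values are the log2 ratios and p-values of the authors' deposited tables, with signs as deposited. If each ratio is the later-named group over the first-named, a positive sign means more transcript in UPS, or in LB in the CTL and LB table. The reverse reading turns every sign in all 3 tables together. Values per library were not used here, so the number of animals that shared a direction is not given.

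The first question was whether Trem2, the lipid-sensing microglial receptor named in the series title as reduced, differed in transcript level between the groups. It did not pass in any pair. In the authors' deposited tables its log2 ratio was -0.013 between CTL and LB (p = 0.716, adjusted p = 0.92), -0.00074 between CTL and UPS (p = 0.984, adjusted p = 0.995) and 0.013 between LB and UPS (p = 0.731, adjusted p = 0.878). The 95% intervals recovered from the authors' deposited tables ran from 0.942-fold to 1.04-fold, from 0.950-fold to 1.05-fold and from 0.959-fold to 1.06-fold, so a transcript difference above about 1.06-fold lay outside each of them. These intervals pool the sexes and take all animals as independent, and they are too narrow if littermates resemble each other. Tyrobp, the signalling adaptor of Trem2, had log2 ratios of 0.025, 0.037 and 0.011 in the authors' deposited tables in that order, and none passed. The title gene may have been picked by the study from its own experiments, and the title does not say whether transcript or protein was meant.

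The comparison of CTL and LB asked whether limited bedding was accompanied by a different microglial transcript profile. None of the 478 genes passed in the authors' deposited table with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.101. With the p-values of the 3 tables adjusted together 3 genes passed between CTL and LB, and 2 passed after centring with a normal test. At an unadjusted p below 0.05 there were 56 genes, 32 with a positive and 24 with a negative ratio, where 23.9 are expected with no difference. Among the smallest p-values in the authors' deposited table was that of Ywhah, a phosphoprotein-binding adaptor, with a log2 ratio of -0.16 (p = 0.000423, adjusted p = 0.101).

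Further small p-values in the authors' deposited table for CTL and LB came with positive ratios of H2-D1, a class I antigen-presenting molecule (0.49), Slc24a3, a sodium-calcium exchanger (0.23), Tmsb4x, an actin-binding peptide (0.099), and Ccl12, a monocyte-attracting chemokine (0.44). Negative ratios of similar p in the authors' deposited table belonged to Cd34, a stem cell and vascular sialomucin (-0.42), Csf3r, the receptor of granulocyte colony-stimulating factor (-0.17), C1qb, a chain of complement C1q (-0.099), and Olfml3, a microglia-enriched secreted protein (-0.17). Each of these 8 had an adjusted p of 0.194. The proliferation marker Mki67 had the largest positive log2 ratio in the authors' deposited table, 1.00, with a wide recovered interval from 0.30 to 1.70 and an adjusted p of 0.198.

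No gene list shifted between CTL and LB by cameraPR on the signed statistic, and several did under other list tests. All 5 measured type I interferon genes had positive ratios in the authors' deposited table, among them Ifit3 (0.64) and Mx1 (0.55), and none passed (list adjusted p = 0.15, 0 past when adjusted over the list alone). Of 12 inflammatory cytokine and NF-kB genes, 10 had positive ratios in the authors' deposited table, with Tnf at 0.42, Il1a at 0.16 and Csf1 at 0.20, and none passed (list adjusted p = 0.15, 0 over the list alone). These 12 genes shifted against random lists of the same size (adjusted p = 0.0017, at the smallest p that 10000 random lists can give) and against random lists matched on standard error (adjusted p = 0.0204), the latter chosen after the data had been seen. Random lists take genes as independent, so their p-values are too small if list members vary together. By cameraPR with a preset correlation of 0.05 the adjusted p of these 12 genes was 0.284. Antigen presentation had 5 of 7 positive ratios in the authors' deposited table (Tap1 0.16, B2m 0.11) and a list adjusted p of 0.419, with 2 genes past when adjusted over the list alone, H2-D1 and the cathepsin Ctss (-0.15). The 4 cell cycle genes included Stmn1 at 0.32 and Ccnb1 at 0.36 in the authors' deposited table (list adjusted p = 0.219, 1 past adjusted over the list alone). Other list tests between CTL and LB called more lists. With log2 ratios as the statistic, the adjusted p was 1.64e-09 for cell cycle, 4.89e-06 for interferon, 0.000697 for inflammatory and 0.0101 for immediate early genes, all positive. Against random lists of the same size it was 0.00255 for cell cycle, 0.0159 for interferon, 0.0180 for antigen presentation and 0.0289 for immediate early genes, all positive, and 0.0180 for oligodendrocyte lineage genes, negative. Against random lists matched on standard error, cell cycle, interferon and antigen presentation each had an adjusted p of 0.0918. Complement had 1 gene, C1qb, past when adjusted over the list alone (list adjusted p = 0.335). The growth factor and cytokine receptor list had 1 as well, Csf3r (list adjusted p = 0.780).

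None of the markers of microglial identity passed between CTL and LB. In the authors' deposited table Cx3cr1, the fractalkine receptor, was at -0.0087, Csf1r, the survival receptor of microglia, at -0.042, and P2ry12, a purinergic receptor of resting microglia, at 0.082. Tmem119, a microglial surface marker, was at -0.19 (adjusted p = 0.492) and Tgfbr1, a TGF-beta receptor that microglia need for their mature state, at -0.071 (p = 0.0306) in the authors' deposited table, beside Olfml3 at -0.17. Of 25 homeostatic genes 14 had a positive and 11 a negative ratio (list adjusted p = 0.910, 0 over the list alone). Of 16 disease-associated genes 5 were positive, and the lysosomal protease Ctsd, at -0.12, had the smallest p of them in the authors' deposited table (list adjusted p = 0.379, 0 over the list alone).

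**Figure D1:**
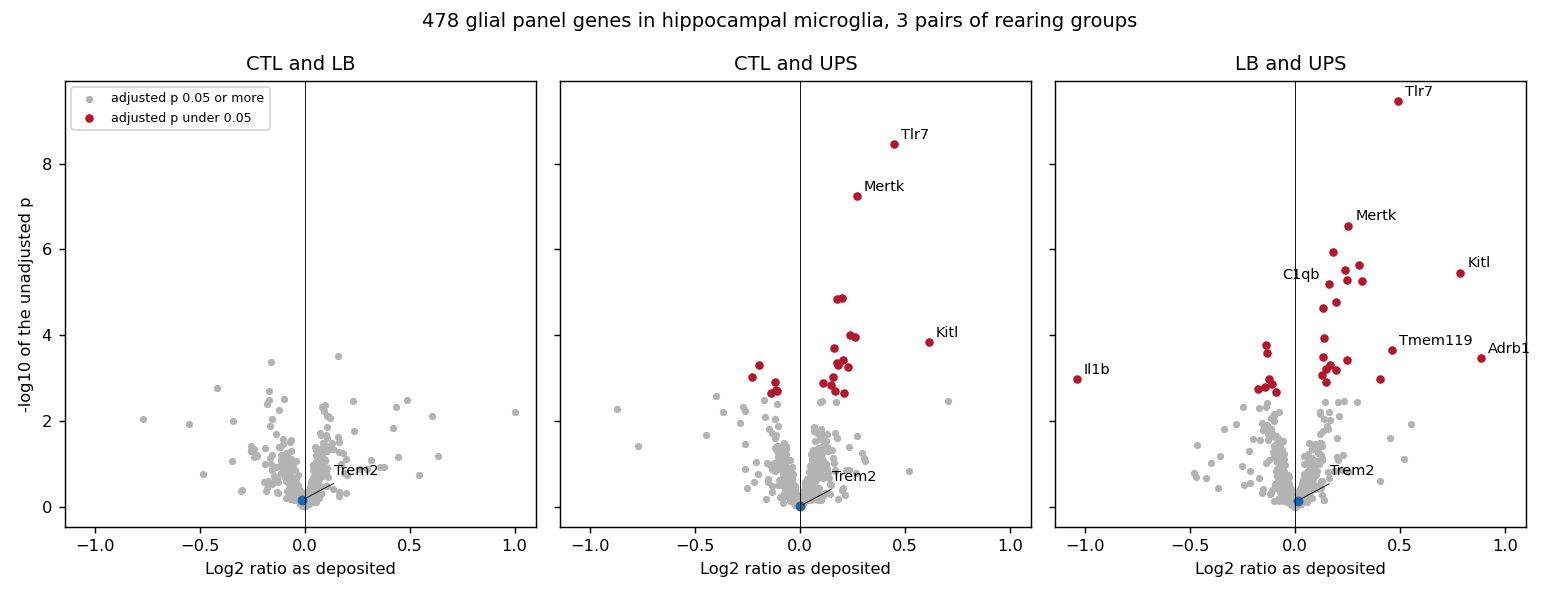
Log2 ratio as deposited (horizontal) against -log10 of the unadjusted p (vertical) for 478 genes in each of 3 pairs of rearing groups, with 1 point per gene. Red points had an adjusted p below 0.05 (0, 23 and 30 genes from left to right), and Trem2, in blue, lies near 0 in each panel.

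The comparison of CTL and UPS asked the same of unpredictable stress. Here 23 of 478 genes passed in the authors' deposited table, 17 with a positive and 6 with a negative ratio, and 78 had an unadjusted p below 0.05. Tlr7, the endosomal receptor of single-stranded RNA, led the table with a log2 ratio of 0.45, or 1.37-fold (recovered 95% interval 0.33 to 0.57, adjusted p = 1.65e-06 in the authors' deposited table). Mertk, the receptor with which phagocytes engulf apoptotic cells, followed with 0.27 (interval 0.19 to 0.36, adjusted p = 1.37e-05 in the authors' deposited table). The differences were small, with a median size of 0.18, and 20 of the 23 were under 1.2-fold.

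Among the positive ratios past the threshold in the authors' deposited table for CTL and UPS, Kitl, the ligand of the KIT receptor, was largest at 0.61. Adrb1, a beta-adrenergic receptor, was at 0.70 in the authors' deposited table and did not pass (adjusted p = 0.0596). Ncf1, a cytosolic subunit of the phagocyte NADPH oxidase, was at 0.26 in the authors' deposited table, Cables1, a Cdk5-binding protein, at 0.24, and Nlrp3, the inflammasome sensor, at 0.23. The glutamate transporter Slc1a3 (0.21), the scavenger receptor Stab1 (0.21), the ubiquitin protease Usp2 (0.20), the PI3-kinase subunits Pik3cb (0.18) and Pik3r1 (0.16), the deubiquitinase Stambpl1 (0.18), the cell cycle transcription factor E2f3 (0.18) and the lipopolysaccharide receptor Tlr4 (0.17) also passed with a positive ratio in the authors' deposited table. Tgfbr1 had 0.11 in the authors' deposited table. Pmepa1 (0.17), a TGF-beta pathway inhibitor, and the endocannabinoid-producing lipase Dagla (0.15) complete the 17 in the authors' deposited table.

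The other 6 genes had negative ratios. In the authors' deposited table for CTL and UPS these were Cysltr1, a leukotriene receptor (-0.23), Tlr2, a receptor of bacterial lipoproteins (-0.19), Cdc23, a subunit of the anaphase-promoting complex (-0.14), Tomm70a, a mitochondrial import receptor (-0.12), Crot, a peroxisomal carnitine acyltransferase (-0.11), and Kcnk13, a potassium channel of microglia (-0.11). Tlr7 and Tlr4 thus carried the opposite sign to Tlr2. The cytokine gene Il1b had a larger ratio, -0.87, in the authors' deposited table, with a wide interval from -1.47 to -0.27, and did not pass (adjusted p = 0.0797).

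No list shifted between CTL and UPS by cameraPR on the signed statistic. Cell cycle passed with log2 ratios as the statistic (adjusted p = 0.0021), and cell cycle and inflammatory genes passed against random lists of the same size (adjusted p = 0.00425 each). On the signed statistic complement, phagocytosis and TREM2 signalling came closest, each with a list adjusted p of 0.120. In the complement list, 4 of 5 ratios were positive and none passed over all genes, while 2 passed adjusted over the list alone, C1qc (0.11) and C1qa (0.069 in the authors' deposited table). Of 15 phagocytosis genes Mertk and Stab1 passed (2 adjusted over the list alone), and P2ry6 at 0.17, Sirpa at 0.097 and Itgam at 0.089 did not in the authors' deposited table. Of 7 TREM2 signalling genes Pik3cb and Pik3r1 passed (2 adjusted over the list alone). Both are PI3-kinase subunits that many receptors share. Of 12 inflammatory genes 3 passed with a positive ratio (Tlr7, Tlr4, Nlrp3) and 1 with a negative (Tlr2), with 5 past adjusted over the list alone and a list adjusted p of 0.136. Adjusted over the list alone, the autophagy gene Atg5 (-0.11 in the authors' deposited table) passed as well. Of 25 genes on the fixed homeostatic list 1 passed, Tgfbr1 (2 adjusted over the list alone, list adjusted p = 0.572). Tmem119 at 0.27, Mef2a, a transcription factor, at 0.096, and Gpr84 at -0.29 in the authors' deposited table did not pass. Whether each member, such as Gpr84, marks a homeostatic state in these cells was not tested. None of 16 disease-associated genes passed (0 over the list alone, list adjusted p = 0.875), and Apoe, the lipid carrier, was at 0.13 in the authors' deposited table (adjusted p = 0.30).

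Markers of other cells were few on the panel, and of 13 measured only Slc1a3 and Stab1 passed between CTL and UPS. Stab1 is also on the phagocytosis list and Apoe on the disease-associated list. In the authors' deposited table for CTL and UPS the astrocyte genes Slc1a3 and Glul were at 0.21 and 0.11, and the border macrophage genes Stab1 and Apoe at 0.21 and 0.13, while the natural killer cell gene Klrd1 was at -0.77 (p = 0.0388, adjusted p = 0.294). The 5 oligodendrocyte lineage genes had 3 positive and 2 negative ratios (list adjusted p = 0.863, 0 over the list alone). The single neuronal (Gad1, -0.047), vascular (Pecam1, 0.033) and neutrophil (Csf3r, -0.062) genes did not pass in the authors' deposited table.

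**Figure D2:**
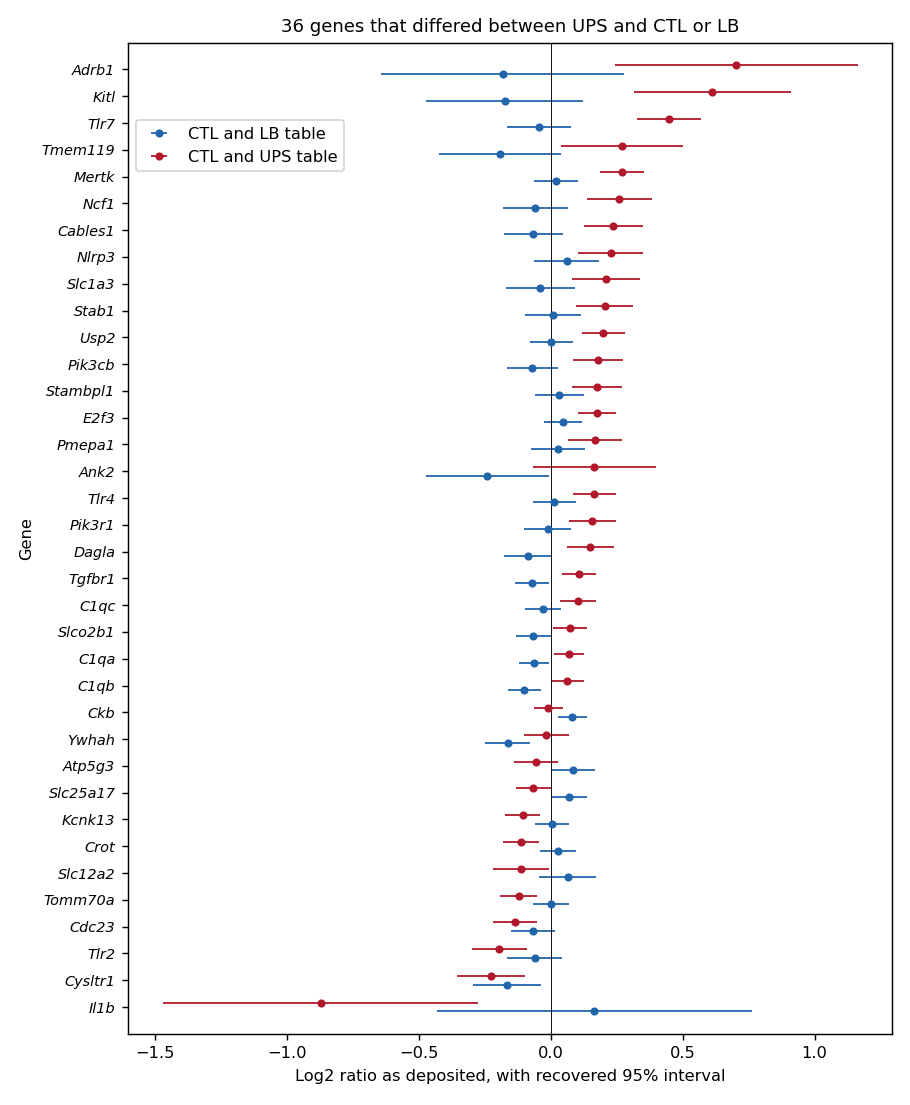
Log2 ratio as deposited (horizontal) with its recovered 95% interval for the 36 genes past an adjusted p of 0.05 between CTL and UPS or between LB and UPS, from the CTL and LB table (blue) and the CTL and UPS table (red). For Tlr7 the red interval runs from 0.33 to 0.57 and the blue from -0.16 to 0.079.

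The comparison of LB and UPS set the stress models against each other. Here 30 genes passed in the authors' deposited table, 22 with a positive and 8 with a negative ratio, and 90 had an unadjusted p below 0.05. The genes of all 3 chains of complement C1q were among them, which opsonises synapses and debris: C1qb at 0.16 (adjusted p = 0.000347), C1qc at 0.13 (adjusted p = 0.00956) and C1qa at 0.13 (adjusted p = 0.00101) in the authors' deposited table. Tlr7 (0.49, adjusted p = 1.66e-07) and Mertk (0.25, adjusted p = 6.67e-05) led this authors' deposited table as well. Il1b had the largest ratio of the authors' deposited table, -1.04 or 0.487-fold, with a recovered interval from -1.64 to -0.44 and an adjusted p of 0.0207.

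Other large positive ratios in the authors' deposited table for LB and UPS belonged to Adrb1 (0.89), Kitl (0.79), Tmem119 (0.46), Ank2, a membrane-cytoskeleton adaptor (0.41), Ncf1 (0.32) and Cables1 (0.30). Slc1a3 (0.25), Pik3cb (0.25), Dagla (0.24), Usp2 (0.20), Stab1 (0.20), Tgfbr1 (0.18), Pik3r1 (0.17) and Tlr4 (0.15) passed with the same sign in the authors' deposited table. Ywhah (0.15), the organic anion transporter Slco2b1 (0.14) and E2f3 (0.13) complete the 22 in the authors' deposited table. The 7 negative ratios besides Il1b in the authors' deposited table were those of the chloride importer Slc12a2 (-0.18), the ATP synthase subunit Atp5g3 (-0.14), the peroxisomal genes Crot (-0.14) and Slc25a17 (-0.13), Tomm70a (-0.12), Kcnk13 (-0.11) and the creatine kinase Ckb (-0.091). The median size was 0.18, and 22 of the 30 were under 1.2-fold.

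Complement was the only list of the 17 to shift between LB and UPS by cameraPR on the signed statistic (adjusted p = 0.0112). Of its 5 measured members the 3 C1q genes passed, also adjusted over the list alone, while Itgam, a subunit of complement receptor CR3, at 0.037 and C3ar1, the C3a receptor, at -0.051 did not in the authors' deposited table. The adjusted p was 0.0254 with a preset correlation of 0.05, and the call was lost with ranks (adjusted p = 0.147), with log2 ratios as the statistic (adjusted p = 0.359), where the type I interferon list passed instead (adjusted p = 0.0323, negative), and with random lists matched on standard error (adjusted p = 0.0612). The C1q genes lie side by side in the genome and are known to be transcribed together, and their correlation in these animals could not be estimated.

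Phagocytosis genes had 11 of 15 positive ratios between LB and UPS, with Mertk and Stab1 past the threshold, 3 past adjusted over the list alone with Sirpa (0.12 in the authors' deposited table), and a list adjusted p of 0.0996. TREM2 signalling had Pik3cb and Pik3r1 past, and Cd33, an inhibitory lectin receptor, at -0.11 in the authors' deposited table passed adjusted over the list alone (3 in all, list adjusted p = 0.161). Of 25 homeostatic genes Tgfbr1 and Tmem119 passed (2 adjusted over the list alone, list adjusted p = 0.459), while P2ry12 at -0.073 and P2ry13 at -0.082 in the authors' deposited table did not. Of 12 inflammatory genes Tlr7 and Tlr4 passed with a positive and Il1b with a negative ratio, and 6 passed adjusted over the list alone. Its median log2 ratio was -0.12 and its mean -0.11, while the cameraPR test leaned to the positive side (list adjusted p = 0.927). Against random lists of the same size the inflammatory list passed on the negative side (adjusted p = 0.0136), and against random lists matched on standard error it did not (adjusted p = 0.0778). The disease-associated list had 10 of 16 positive ratios and none past the threshold (0 over the list alone, list adjusted p = 0.546).

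The remaining lists did not shift in any pair by cameraPR on the signed statistic. On it the adjusted p between LB and UPS was 0.769 for lysosome, 0.771 for autophagy, 0.228 for cholesterol and lipid handling, 0.520 for interferon, 0.459 for antigen presentation, 0.546 for cell cycle, 0.891 for glycolysis and hypoxia, 0.771 for immediate early genes, 0.508 for TGF-beta signalling, 0.927 for growth factor and cytokine receptors and 0.432 for oligodendrocyte lineage genes. Against random lists of the same size interferon genes passed between LB and UPS on the negative side (adjusted p = 0.0402), and against random lists matched on standard error they did not (adjusted p = 0.0778). Over the list alone, Tgfbr1 and Tgfb1 (-0.076 in the authors' deposited table) passed for TGF-beta signalling and Plxnb3 (0.29 in the authors' deposited table) for the oligodendrocyte lineage, and none in the others of these lists. Between LB and UPS the astrocyte genes Slc1a3 and Glul were at 0.25 and 0.15 and the border macrophage genes Stab1 and Apoe at 0.20 and 0.13 in the authors' deposited table. In the same authors' deposited table Csf3r was at 0.11, Klrd1 at -0.47, Gad1 at 0.0029 and Pecam1 at 0.068. Mertk was the only measured gene of the glucocorticoid-responsive list.

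**Figure D3:**
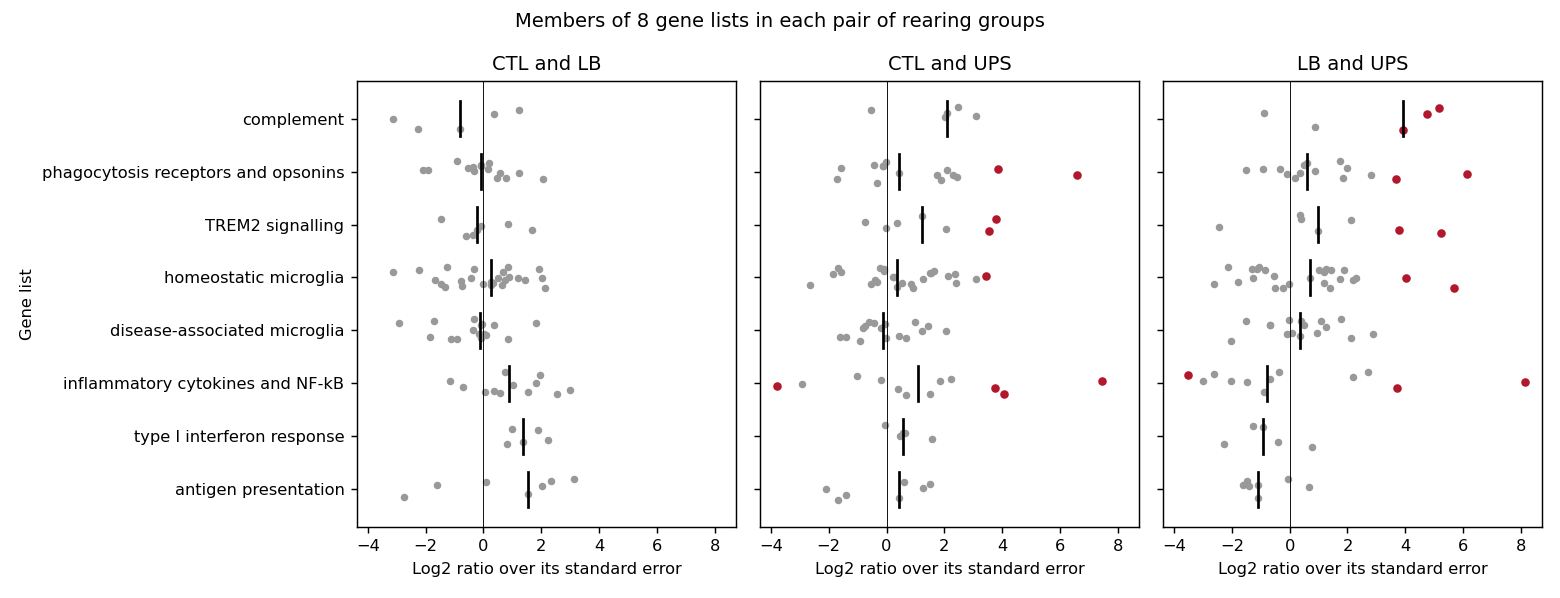
Log2 ratio divided by its recovered standard error (horizontal) for each measured member of 8 gene lists (rows) in each pair of rearing groups, with 1 point per gene and a black bar at the list's median. Red points passed an adjusted p of 0.05 over all genes, and in the complement row they are the 3 C1q genes between LB and UPS.

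Both comparisons with UPS shared 17 genes past the threshold, all with the same sign, 14 positive and 3 negative. Independent lists of these sizes would share 0.782 and 0.10. Unchanged groups shared a mean of 0.005 genes in simulation, where almost no gene passes, so that value does not cover lists of these lengths. The pairs share the 16 UPS libraries, so part of this overlap may come from them, and without values per library the UPS group could not be split. Of the shared genes, the naming rule gave Tlr7, Mertk, Usp2, Cables1, Ncf1, Kitl, Pik3cb, Tlr4, Stab1, E2f3, Pik3r1 and Tomm70a. Tgfbr1, Dagla, Slc1a3, Crot and Kcnk13 were shared as well. The ratios of all these genes in the authors' deposited tables are given above, and the negative ones are Tomm70a, Crot and Kcnk13. Passing in 1 pair only, as Nlrp3, Tlr2 and Cysltr1 did between CTL and UPS, does not show a difference between pairs.

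The LB and UPS ratios against CTL were also set against each other across the 478 genes, which are not independent replicates. Pearson's r was 0.39, where unchanged groups that share the CTL libraries gave a mean of 0.50 (0.31 to 0.66), and Spearman's rho was 0.38 (simulated mean 0.46). The covariance was 0.00621 against a simulated 0.00374 (0.00199 to 0.00582), and so lay above the simulated range. Among the 239 genes with a standard error below the median, r was 0.20 against a simulated 0.50 (0.39 to 0.60). Their covariance was 0.000567 against 0.000727 (0.000512 to 0.000965). The simulation drew genes independently, so its ranges are too narrow if genes vary together. The ratios of 63.0% of genes had the same sign in both tables, against 66.8% in the simulation.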

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

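The tests in this part were chosen after the ratios had been seen, except the test of Il1b, whose outcomes were set before the companion transcripts were examined. The LB and UPS changes against CTL differed for 30 genes, since the authors' deposited table of LB and UPS tests that difference itself. Their log2 differences, as deposited, were 0.89 for Adrb1, 0.79 for Kitl, 0.49 for Tlr7, 0.46 for Tmem119, 0.41 for Ank2, 0.32 for Ncf1, 0.30 for Cables1, 0.25 for Mertk, 0.25 for Slc1a3, 0.25 for Pik3cb, 0.24 for Dagla, 0.20 for Usp2, 0.20 for Stab1, 0.18 for Tgfbr1, 0.17 for Pik3r1, 0.16 for C1qb, 0.15 for Tlr4, 0.15 for Ywhah, 0.14 for Slco2b1, 0.13 for C1qc, 0.13 for C1qa and 0.13 for E2f3. Negative differences were -1.04 for Il1b, -0.18 for Slc12a2, -0.14 for Atp5g3, -0.14 for Crot, -0.13 for Slc25a17, -0.12 for Tomm70a, -0.11 for Kcnk13 and -0.091 for Ckb.

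The first pattern is that no gene passed between CTL and LB while 23 passed between CTL and UPS, each table adjusted by itself, where adjusting the 3 tables together gave 3 and 18. A single offset shared by all genes in the deposited ratios is argued against as the whole of it, because the median log2 ratio of all genes was -0.00245 (95% bootstrap interval over genes -0.011 to 0.0042) where the genes that passed had a median size of 0.18, 17 positive and 6 negative. Normalization can remove such an offset, so an offset present before it would not show in this median. RNA of other cells in the UPS libraries stays open: 4 of 13 measured markers had an unadjusted p below 0.05, 3 positive (Apoe, Slc1a3, Stab1) and 1 negative (Klrd1), too few to decide. Cells were sorted by flow cytometry, and how far the sort removed other cells, such as border macrophages, was not tested. Stab1 and Apoe are not markers of border macrophages alone, since Apoe is also on the disease-associated microglia list and Stab1 on the phagocytosis list. A rearing effect on microglia, which the design names, may account for the pattern and was not separated from RNA of other cells. Differences between litters, 4 to 5 per group and sex, were not separated from rearing either, since litter was not used here.

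The second pattern is the difference between LB and UPS. Of the 30 genes, 17 also passed between CTL and UPS, although both pairs share the 16 UPS libraries. For these 17 a change in LB alone is argued against. It stays open for the other 13, of which 7 had an unadjusted p below 0.05 between CTL and UPS, a number raised by picking them on LB and UPS, while Ywhah (-0.16 between CTL and LB, -0.016 between CTL and UPS) and Ckb (0.083 and -0.0084) in the authors' deposited tables had CTL near UPS. A change in UPS alone stays open too: UPS differed from the mean of CTL and LB for 34 genes, and for 24 of them LB lay on the other side of CTL from UPS, where 17 are expected if LB does not differ from CTL (exact binomial test, two-sided, p = 0.0243 if genes were independent). Since genes of the same animals are not independent, and the bounds for this test were set with its values known, opposite small shifts of LB and UPS in genes such as C1qb (-0.099 and 0.064 in the authors' deposited tables) remain a hypothesis.

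The third pattern is the Il1b ratio of -1.04 between LB and UPS. If transcripts induced while cells were isolated set it, other such transcripts would share its sign and pass. Of 8 (Fos, Jun, Egr1, Ccl3, Ccl2, Ccl12, Tnf and Il1a), 7 shared the sign, but only Il1a had an unadjusted p below 0.05 (-0.25 in the authors' deposited table, adjusted p = 0.0614), and none passed with the opposite sign. Between CTL and LB, Il1b (0.17) and all 8 had positive ratios in the authors' deposited table. Between CTL and UPS, Il1b was at -0.87 and Il1a at -0.084. The other 7 were positive in that pair: Fos 0.11, Jun 0.056, Egr1 0.203, Ccl3 0.086, Ccl2 0.113, Ccl12 0.222 and Tnf 0.305. Most thus shared the sign of Il1b between LB and UPS but not between CTL and UPS. None of the 8 had an unadjusted p below 0.05 between CTL and UPS. Induction during isolation and a rearing effect on Il1b therefore cannot be told apart with these transcripts.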

How the results depend on the processing

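The random lists matched on standard error, the moderated variances and the ratios per standard error were added after the data had been seen. Between CTL and LB the count of 0 genes became 56 at an unadjusted p below 0.05, 3 with the 3 tables adjusted together and 2 after centring with a normal test, which gave 31 and 41 genes in the other pairs. That setting changed both the centring and the reference distribution, and the cause was not tested. Between CTL and UPS the 23 genes became 78 unadjusted, 4 with the Benjamini-Yekutieli method and 3 with a minimum of 1.2-fold. Between LB and UPS the 30 genes became 90 unadjusted, 48 at an adjusted p below 0.10, 13 with Benjamini-Yekutieli and 8 with 1.2-fold. The counts at other thresholds, adjustments and minimum sizes follow from stricter or looser rules. Moderated variances gave 0, 24 and 34 genes, with all 23 and all 30 among them.

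For gene lists, log2 ratios as the statistic gave 4 lists between CTL and LB and 1 between CTL and UPS in place of 0. Between LB and UPS they gave 1, the type I interferon list (adjusted p = 0.0323, negative) and not complement. Random lists, which take genes as independent, gave 6, 2 and 3 lists in the order of the tables in place of 0, 0 and 1. Several of these hold genes with large standard errors, such as the cell cycle genes with a median of 0.20 against 0.050 for all genes. Matched on standard error, random lists gave 1 list (inflammatory) between CTL and LB, 0 between CTL and UPS and 0 between LB and UPS. Ranks gave 0 lists between LB and UPS. The inflammatory list between LB and UPS turned from a positive to a negative side under random lists (adjusted p = 0.0136), since its median is negative while its signed statistics average 0.044. The adjusted p of complement between LB and UPS ranged from 0.00523 to 0.359 over its alternatives.

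The correlation of LB and UPS ratios became 0.20 among genes with small standard errors (0.50 in simulated unchanged groups, 0.39 to 0.60). With ratios per standard error it became 0.29 (simulated 0.50, 0.43 to 0.57). Both lay below the simulated range, which takes genes as independent, and the cause was not tested. The covariances of these settings lay within their simulated ranges, at 0.000567 (0.000512 to 0.000965) and 0.577 (0.405 to 0.603). The covariance of all 478 genes, 0.00621, lay above its simulated range (0.00199 to 0.00582). For the 455 genes that passed in neither pair with CTL it was 0.00676, also above its range (0.00207 to 0.00591). Their correlation of 0.45 lay within its range (0.32 to 0.65). Trem2 passed in no pair under any alternative run. Of single genes named, 32 results lost their call with Benjamini-Yekutieli and 6 with the tables adjusted together. No paired analysis was possible because the tables hold no values per library. For the same reason fits without a library, with batch as a block or on other splits of the animals were not run, and the limits of depth are unknown.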

Other observations

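The families in this part were chosen after the data had been seen, and the outcome for LB and UPS was set before their tests were run. The panel also holds families of genes related by symbol or by function, and 12 of them were tested with cameraPR. Family p-values were adjusted over the 12 families of each pair and not over the 3 pairs together. Members of 4 families are also in fixed lists: Tlr2, Tlr4 and Tlr7, Pik3cb and Pik3r1, Psmb8, and Atp6v0d1 and Atp6v1h. Between CTL and UPS, 5 genes of peroxisomal fatty acid metabolism all had negative ratios, with Crot past the threshold at -0.11 and Hsd17b4 at -0.11 in the authors' deposited table (family adjusted p = 0.0376). Between LB and UPS 3 of the 5 had positive ratios, with Crot and Slc25a17 past the threshold on the negative side (family adjusted p = 0.23). Of 12 genes of cullin and anaphase-promoting ubiquitin ligases, 11 had negative ratios, with Cdc23 past the threshold at -0.14 and Cul1 at -0.10 in the authors' deposited table (family adjusted p = 0.0376), and 9 were negative between LB and UPS (family adjusted p = 0.129). All 7 proteasome genes were negative as well, with Psmd14 at -0.076 in the authors' deposited table (family adjusted p = 0.0715), and between LB and UPS.

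The hypothesis that at least 1 family shifts between LB and UPS was not borne out at an adjusted p below 0.05. The smallest was 0.0591, shared by the Toll-like receptors, the proteasome and the PI3K, Akt and mTOR family. The Toll-like receptor and PI3K values rest largely on genes already described. The 4 Toll-like receptor genes did not share a sign. Tlr7, Tlr4 and Tlr3 had ratios of 0.49, 0.15 and 0.095 between LB and UPS in the authors' deposited table, of which Tlr3 did not pass, and Tlr2 was negative. Between CTL and LB no family had an adjusted p below 0.779.

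The deposited tables also allow the test of any rearing difference over the 3 groups to be rebuilt. It gave 95 genes at a p below 0.05 and 33 at an adjusted p below 0.05. The series text states 87 genes for rearing from a model that also held sex, run on genes above 20 counts. It also states 13 genes for sex and 5 for the interaction. The model and threshold behind the 87 were not matched here, so neither rebuilt count can be set against it. CTL differed from the mean of LB and UPS for 0 genes, UPS from the mean of the others for 34 and LB for 13. For 12 of these 13 the CTL and UPS ratio had the opposite sign, as a change in UPS alone would also give, and 0 genes passed between CTL and LB.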
